A study of Homo sapiens with 3 samples.

How the data were processed

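The series holds 3 RNA-seq libraries of TC32, an established Ewing sarcoma cell line whose growth depends on the fusion protein EWS-FLI1. One library came from control cells, 1 from cells with knockdown of EWS-FLI1, and 1 from cells treated at 3 µM for 15 hours with a compound named here YK, as in the title of that library. The compound is a small molecule described as blocking the binding of EWS-FLI1 to the RNA helicase DHX9. The labels name DMSO as the vehicle of the compound and do not say whether the control received vehicle or a control hairpin, nor how long the knockdown lasted. The values of the knockdown library are headed dEF while its title reads shEF, and the library was taken as the knockdown from its labels. Per the labels' protocols, cDNA was made from total RNA with a SMARTer kit, sheared by sonication and amplified by ligation-mediated PCR before sequencing.

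The values used are FPKM, which the authors deposited for 88434 loci in each library. By the plain definition these are fragments relative to locus length in kilobases and to the mapped fragments of the library. Per the submitters' processing notes, the tools were CASAVA 1.8.2, TopHat and Cufflinks 2.2.1, and the genome build was GRCh37 (hg19). The scaling that the authors applied between libraries, the annotation, the filters and the handling of reads that map to several places are not given in the sources used here. The row names mark loci merged over the libraries, with no coordinates, lengths, estimation status or confidence bounds used here. A gene name stood on 24751 loci and 63683 loci had none. Some gene names join neighbouring or overlapping genes in 1 locus, 767 names in all, and these were kept as they stood.

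Loci with the same gene name were summed, which left 22714 names, and 9939 of them had a mean FPKM of at least 1 over the 3 libraries and were compared. Ratios are differences of log2(FPKM + 1), which understate the change of genes with low values. A gene was called higher or lower at an absolute log2 ratio of at least 1. With 1 library per group there is no spread between replicates, so no test was made and no p-value is given, and the words higher and lower describe these libraries. The design, the 25 gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The lists were written from general knowledge, and some genes stand on more than 1 of them.

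The deposited FPKM of the named genes differed in overall scale between libraries, with a median log2 ratio to control of -1.75 in the knockdown library and -2.20 with YK. The counts of genes are therefore given as deposited, as planned, and again after scaling. The scaling divided each library by the median, over named genes above 0 in all 3 libraries, of its ratio to the gene's geometric mean, before the value of 1 was added. It multiplied the control by 0.325, the knockdown library by 1.44 and the YK library by 2.12. This scale was chosen after seeing the data, because adding 1 to libraries whose values lie several-fold apart moves scarce and abundant genes differently. The planned remedy, centring the deposited log2 ratios on their median, has that flaw and is given as an alternative. The values of single genes and of gene lists are on the added scale, and "relative log2 ratio" means the difference of log2(scaled FPKM + 1). The choice assumes that the median named gene did not differ between libraries. A change of all messenger RNA together could not be seen. The filter on mean FPKM and the bins of expression used deposited values, in which the control weighs most. A gene found only in a treated library thus needed a higher scaled value to be compared than 1 found only in the control.

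Depth was estimated from the steps in low values. In 1 kb, 1 fragment was worth about 0.0654 FPKM in the control, 0.0174 in the knockdown library and 0.0127 with YK. These came from single-transcript olfactory receptor genes at their lowest values. Ratios of low unnamed loci put the worth in the control at 3.77 times that in the knockdown library and 4.98 times that with YK. Fragments were estimated from the olfactory value of the control and these ratios. Those ratios lay within 0.01 log2 of whole steps of up to 8 fragments for 27.3% of loci between control and knockdown, against 4.08% on average over other shifts, and for 17.6% against 3.95% between control and YK. With transcript lengths from GENCODE release 29, which matched 8750 of the 9939 genes (88%), this gave about 24501270, 14788900 and 18050178 fragments in the control, knockdown and YK libraries over the compared genes. For the control this is more than the plain definition of FPKM allows at that worth of 1 fragment, so its values may hold a further scaling. Standard errors of log2 ratios come from these estimated fragments. They cover counting error only, are approximate, and hold nothing of the spread between cultures or preparations. The reference annotation belongs to another build and was used for lengths, GC content and names alone.

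For each list, the median relative log2 ratio of its measured members was set against 10000 random lists of the same size matched in 20 bins of expression, and its percentile among them describes these libraries. Intervals of list medians are bootstrap 95% intervals over genes from 2000 draws. Both treatments were compared with the same control library, so 100 sets of 3 unchanged libraries were drawn from Poisson counts at the estimated depth to show what a shared control gives by counting error. The procedure was tested on simulated data over 8750 genes with 200 changed genes in each comparison. For knockdown against control it called 9.33% of 2-fold, 96.6% of 4-fold and 98.5% of 8-fold changes, for YK against control 7.81%, 86.1% and 93.8%, and for YK against knockdown 15.9%, 93.2% and 93.1%. No unchanged gene was called in any of them. The simulated data held counting error alone, with no spread between cultures or preparations. They therefore give no rate of false calls for the real libraries.

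EWS-FLI1 and its partner DHX9 were looked at first, through FLI1, EWSR1 and DHX9. For each comparison with the control, the 10 highest and 10 lowest genes by the deposited log2 ratio were then taken, and for YK against knockdown the 5 highest and 5 lowest. Names of small RNAs, unnamed transcripts and ribosomal protein pseudogenes, and genes under 300 nt, were left out, and up to 2 highest and 2 lowest members of each list could be named. Some genes that this rule takes are not reported here. Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling to a common sum of all loci, centring, the highest locus per name, and a threshold of 2. Added after seeing the data were the scaling above, division by the worth of 1 fragment, a correction for expression level, length and GC content in 10 bins each, and counting merged loci in the lists. Alternatives on estimation status and on confidence bounds were not run. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.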

Results

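Messenger RNA was profiled in 3 RNA-seq libraries of TC32 Ewing sarcoma cells, 1 from control cells, 1 after knockdown of EWS-FLI1 and 1 after 15 hours in 3 µM of the compound YK, a small molecule described as blocking the binding of the fusion protein to DHX9. The series asks how loss or chemical inhibition of the EWS-FLI1 fusion alters expression, with the G2/M phase of the cell cycle and the response to the microtubule drug vincristine in view. There was 1 library per group, so no value below has a replicate check and no p-value is given. The compared genes held about 24501270 estimated fragments in the control, 14788900 in the knockdown library and 18050178 with YK. Deposited values are given as FPKM, and standard errors (SE) cover counting error only.

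The transcripts tied to the fusion were examined first. Reads of the fusion fall on EWSR1, which gives its 5' part, and on FLI1, which gives the DNA-binding part. FLI1 stood at 65.9 FPKM in the control, 1.48 in the knockdown library and 8.29 with YK. Scaled on the median gene, FLI1 had 21.4 FPKM in the control, 2.13 in the knockdown library and 17.6 with YK. With 1 added to these values, FLI1 was 7.15-fold lower in the knockdown library (relative log2 ratio -2.84, SE 0.06) and 1.21-fold lower with YK (-0.27, SE 0.04). EWSR1, which the unrearranged allele also transcribes, had 247 FPKM in the control, 40.7 in the knockdown library and 36.3 with YK, and its relative log2 ratios were -0.45 and -0.06. DHX9, the RNA helicase that binds the fusion protein, had 412, 35.8 and 41.3 FPKM, with relative log2 ratios of -1.36 in the knockdown library and -0.61 with YK. Abundant genes such as DHX9 were generally low in the knockdown library. The median there was -0.96 in the most abundant of 5 equal groups of genes ranked by level with YK. FLI1 was thus low in the library labelled as knockdown, whose values stand under the heading dEF while its title reads shEF, and near the median gene's shift in the library of the compound.

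As deposited, most named genes had lower FPKM in both treated libraries. Of 9939 genes, 301 were higher and 7094 lower in the knockdown library, and 57 were higher and 9160 lower with YK. Without a pseudocount the median named gene was 4.42-fold lower in the knockdown library and 6.36-fold lower with YK. Loci without a gene name did not share this shift, with median log2 ratios of 0.23 and 0.35. After scaling on the median named gene, 1715 genes were higher and 1689 lower in the knockdown library, and 240 were higher and 168 lower with YK. Centring the deposited ratios instead gave 2206 higher and 2342 lower in the knockdown library and 1225 higher and 446 lower with YK.

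**Figure D1:**
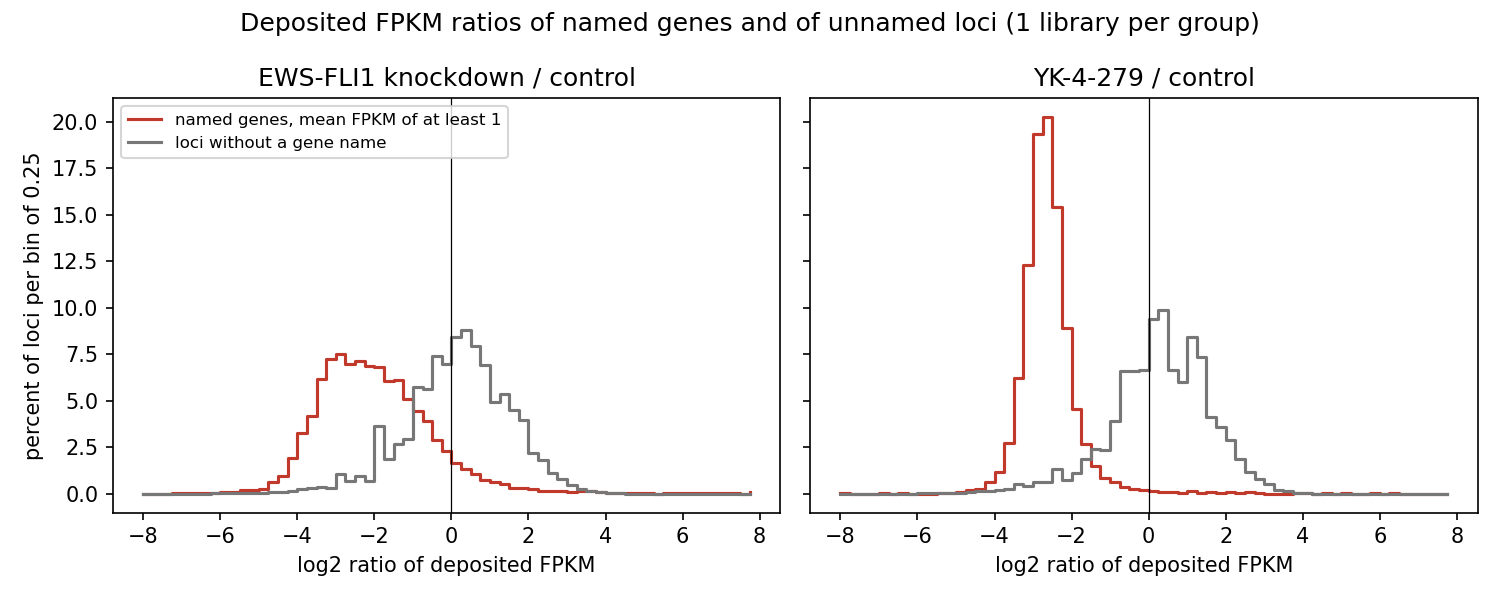
Distribution of log2 ratios of deposited FPKM to control for named genes and for loci without a gene name, in percent of loci per bin of 0.25, for the knockdown library (left) and the YK library (right). Named genes lie to the left of 0, with medians of -2.14 and -2.67, while unnamed loci lie around 0.23 and 0.35.

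Matrix and mesenchymal genes were high after knockdown of EWS-FLI1, with 21 of 24 measured above the threshold. Among the 10 highest of all genes, CPA4, a carboxypeptidase, had 258 FPKM against 0.246 in the control (relative log2 ratio 8.43, SE 0.05). FABP4, a fatty acid carrier, had 78.9 against 0.103 (6.79, SE 0.04), and EFEMP1, a matrix glycoprotein, had 87.4 against 0.349 (6.83, SE 0.09). FN1, which encodes fibronectin, had 116 against 1.92 FPKM (6.69, SE 0.04), and ACTA2, smooth muscle actin, had 83.3 against 0.778 (6.59, SE 0.09). The remaining genes among the 10 highest were GPNMB at 6.75, MGP, a matrix protein of cartilage and vessel wall, at 6.61, PTX3 at 6.32, DKK1, a secreted Wnt antagonist, and the merged locus KRT19P2,MIR492. The last pair was listed at 0 in the control and at 39.5 and 298 FPKM in the knockdown library, so no fold is given.

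The 10 lowest genes in the knockdown library began with the nuclear RNA MALAT1, which was listed at 0 there against 563 FPKM in the control and 241 with YK. Such a 0 can be a locus that was not estimated, so no fold or direction is drawn from it. The related genes MBD3L2, MBD3L3 and MBD3L5 had relative log2 ratios of -4.72, -3.95 and -3.57, and since they are near-identical copies their reads may have been divided among them. CES1, a carboxylesterase, had 112 FPKM in the control and 1.32 in the knockdown library (-3.69, SE 0.08). UGT3A2, a glycosyltransferase on the list of fusion targets, had 269 and 5.62 FPKM (-3.28, SE 0.05), and SCNN1G, a subunit of the epithelial sodium channel, had 84.3 and 1.14 (-3.42, SE 0.06). ISOC1 and WDR18 stood at -3.88 and -3.81, and the merged locus RNF149,SNORD89 at -5.11.

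Genes listed as activated by EWS-FLI1 were low in the knockdown library. Of 40 measured, 19 were lower, 2 were higher and 19 were neither, and their median relative log2 ratio of -0.95 (bootstrap interval -1.46 to -0.41) lay below all 10000 random lists. UGT3A2 and NR0B1, an orphan nuclear receptor, were the lowest, NR0B1 at 117 FPKM in the control and 3.29 in the knockdown library (-2.76). CALCB, a calcitonin-related peptide, and PAPPA, a protease of IGF-binding proteins, were the 2 higher members, at 3.04 and 2.11. Genes listed as repressed by the fusion went the other way, with 22 of 27 higher, 2 lower and a median of 3.19 (2.33 to 5.33), above all random lists, which was 4.88 with a pseudocount of 0.1 and 4.81 among genes with a mean FPKM of at least 5. FN1 and ACTA2 led that list, while S100A4 and S100A6, small calcium-binding proteins, were its lower members at -1.37 and -1.01. Matrix and mesenchymal genes had 21 of 24 higher and a median of 3.20, above all random lists, which was 1.96 without a filter on low values. Of the 4 measured fibroblast markers, FAP, PDGFRB and LUM were also higher in this library, at 1.86, 1.44 and 1.34, and DCN was lower at -1.86. SPARC, a matrix glycoprotein, had 724 FPKM against 23.5 (6.92), and TWIST1, a mesenchymal transcription factor, was the 1 lower member at -1.62.

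Genes of DNA replication were low in the same library. Of 46 G1/S and DNA replication genes, 30 were lower and 0 higher, and the median of -1.58 (-1.81 to -1.21) lay below all random lists. The replication kinase CDC7 and the replication factor GINS1 were the lowest, at -2.77 and -2.68. Of 48 G2/M and mitosis genes, 22 were lower and 1 higher, with a median of -0.98 (-1.19 to -0.86) at percentile 2.5, the edge of the middle 95% of random lists, whose median was -0.72. Aurora kinase AURKB had 464 FPKM in the control and 17.2 in the knockdown library (-2.56), PBK stood at -2.28, and WEE1, the kinase that holds CDK1 inactive, was the 1 higher gene at 1.92. The G2/M list lay at percentile 4.42 on deposited values, and corrected for expression level, length and GC content its median was -0.35 at percentile 3.03.

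Tubulins and microtubule-associated proteins had no common direction after knockdown, with 5 of 32 higher, 8 lower and a median of -0.31 at percentile 37.5. TUBA1B, an abundant alpha-tubulin, had 8271 FPKM in the control and 380 in the knockdown library (-2.29), and MAPT, which encodes tau, had 54.8 and 2.09 (-2.23). MAP1B and CLIP1, both microtubule-binding proteins, were the highest at 2.16 and 2.11. The APC/C and SCF ubiquitin ligase genes had 9 of 25 lower and 0 higher, with a median of -0.92 at percentile 4.58, with SKP2 at -2.38 and CKS1B at -2.29. Corrected for expression level, length and GC content, their median was -0.056 at percentile 53.5.

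Immediate early and MAPK feedback genes had 9 of 13 higher in the knockdown library and a median of 1.34 at percentile 99.9, or 2.10 with a pseudocount of 0.1, with the phosphatase DUSP6 at 2.98 and PHLDA1 at 2.92. The integrated stress response and unfolded protein response list had 11 of 27 higher and 2 lower, with a median of 0.65 at percentile 99.9, NUPR1 at 4.69, ATF3 at 2.24 and the serine synthesis enzyme PSAT1 at -1.84. NRF2 targets had 7 of 16 higher and a median of 0.65 at percentile 99.8, with the transporter ABCC1 at 2.49 and the haem oxygenase HMOX1 at 2.05, although the median was -0.17 among genes with a mean FPKM of at least 5. Splicing factors and RNA helicases had 10 of 38 lower and 2 higher, with a median of -0.08 at percentile 99.8, which was -0.39 on deposited ratios relative to the median gene, -0.37 among genes with a mean FPKM of at least 5 and 0.26 after correction for expression level, length and GC content. Cytosolic ribosomal proteins had 11 of 65 lower and a median of -0.78 at percentile 99.0, where other genes of their abundance were lower still. It was 0.10 after that correction and -1.17 on deposited ratios relative to the median gene. Fibroblast and endothelial markers, with 4 of 11 measured, had a median of 1.39 at percentile 98.3, or 0.81 without a filter on low values, and all 4 had at least 1 FPKM in the control.

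The other lists lay within the middle 95% of random lists after knockdown, but after correction for expression level, length and GC content interferon response genes lay at percentile 98.5 and cholesterol synthesis at 98.4. Interferon response genes had a median of 0.67 with 6 of 19 higher, p53 targets 0.26 with 3 of 18 higher and 3 lower, and cholesterol synthesis 0.12 with 8 of 24 higher and 2 lower. Hypoxia and glycolysis genes stood at 0.12, neuronal markers at 0.12, replication-dependent histones at 0.11 and the BCL2 family at -0.16. Heat shock genes had a median of -0.88 with 8 of 17 lower, and proteasome subunits -1.12 with 21 of 31 lower, at percentiles of 13.4 and 18.8. Abundant genes were generally low in this library, with a median of -0.96 in the most abundant and 0.65 in the least abundant of 5 equal groups of genes ranked by their level with YK, so values of abundant and scarce genes carry that trend.

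After scaling, fewer genes passed the threshold with YK than after knockdown, while as deposited more did. LGALS1, the sugar-binding protein galectin-1, had 251 FPKM against 15.2 in the control (relative log2 ratio 6.49, SE 0.11). CCK, the peptide cholecystokinin, had 38.1 against 0.634 (6.08, SE 0.09), ACTA2 had 26.6 against 0.778 (5.51, SE 0.10) and MGP had 18.3 against 0.220 (5.21, SE 0.08). PSMB8, a subunit of the immunoproteasome, had 6.64 against 0.0752 FPKM (3.88), DNAJC15, a mitochondrial co-chaperone, had 5.52 against 0.106 (3.62), and PENK, proenkephalin, had 4.23 against 0.178 (3.23). The metallothionein MT1E was listed at 0 in the control and at 4.68 FPKM with YK. The remaining pair among the 10 highest were merged loci with small nucleolar RNAs, SNHG12,SNORA44,SNORA61 at 4.76 and CCT6P1,SNORA22 at 4.38.

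The cytokine MIF had 3007 FPKM in the control and 22.2 with YK (-4.35, SE 0.04), after the merged locus RNF149,SNORD89 at -5.82. WDR18 and ISOC1 stood at -4.24 and -3.43, close to the ends of the knockdown comparison, which used the same control library. MRPL12, a mitochondrial ribosomal protein, was at -3.52 and LY6E at -2.56. CCNE2, cyclin E2 of the G1/S transition, had 261 FPKM in the control and 6.73 with YK (-2.49, SE 0.04). EIF4EBP1, a repressor of translation, was at -2.36 and ABCF3 at -2.26.

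**Figure D2:**
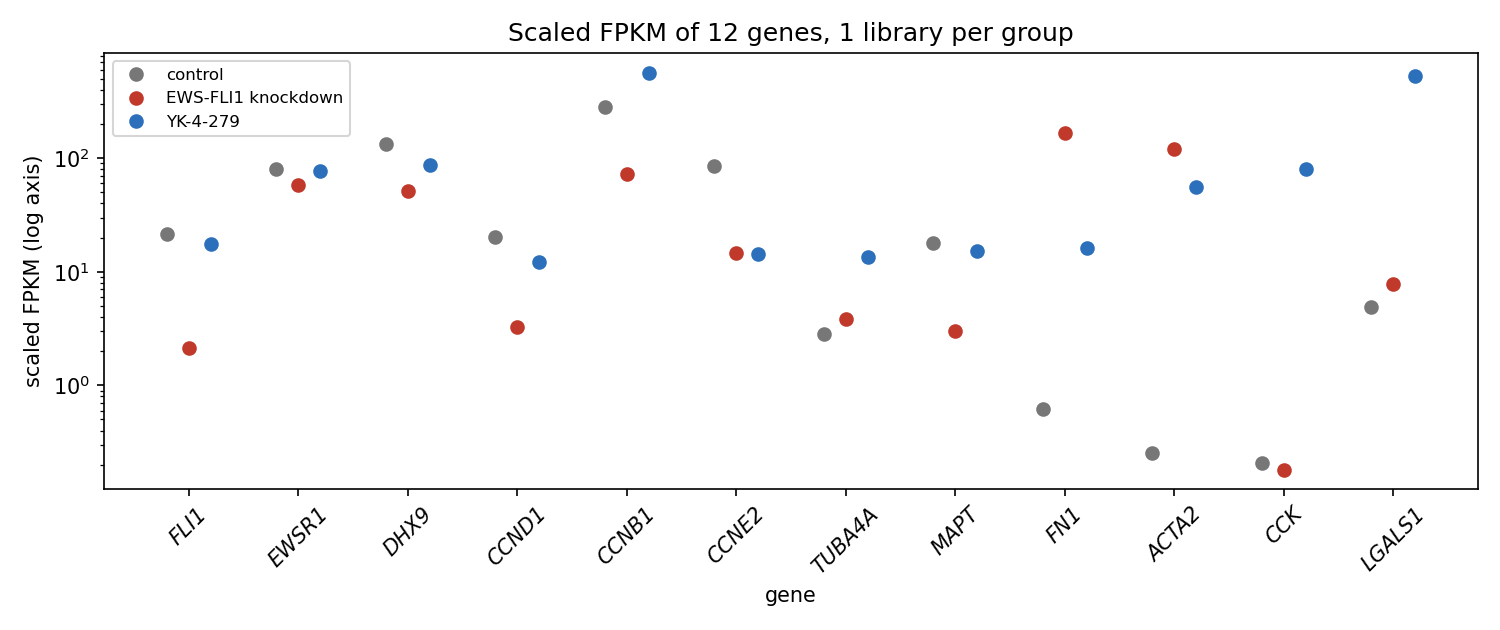
Scaled FPKM, on a log axis, of 12 genes in the control, knockdown and YK libraries, each point 1 library without an error. FLI1 is low in the knockdown library alone, FN1 and ACTA2 are above the control in both treated libraries, and CCK and LGALS1 stand high with YK.

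Genes listed as repressed by EWS-FLI1 were also high with YK, with 13 of 27 higher, 0 lower and a median of 0.90 (0.53 to 1.39) above all random lists. That median was 1.94 on deposited ratios relative to the median gene, 1.54 with a pseudocount of 0.1 and 0.58 without a filter on low values. ACTA2 and S100A6 led, S100A6 with 73.7 FPKM against 16.6 in the control (4.62), although S100A6 was lower in the knockdown library. Matrix and mesenchymal genes had 5 of 24 higher and a median of 0.47, above all random lists, or 0.83 on deposited ratios relative to the median gene, with FN1 at 3.40 and SPARC at 2.71. Genes listed as activated by the fusion were not low with YK, with 6 of 40 higher, 0 lower and a median of 0.16 (-0.09 to 0.35) at percentile 99.6, which was 0.024 on deposited ratios relative to the median gene and 0.088 among genes with a mean FPKM of at least 5. CCK, itself on that list, and the lipase ABHD6 were the highest, at 6.08 and 2.03.

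The 2 cell cycle lists parted with YK. Of 46 G1/S and DNA replication genes, 9 were lower and 0 higher, with a median of -0.39 (-0.57 to -0.24) below all random lists, or -0.85 on deposited ratios relative to the median gene, and CCNE2 and the replication licensing factor CDC6 were the lowest at -2.49 and -1.55. Of 48 G2/M and mitosis genes, 1 was higher and 0 lower, and the median of 0.28 (0.21 to 0.40) lay above all random lists, but was -0.11 on deposited ratios relative to the median gene. GTSE1, a G2 and S phase protein, was that 1 gene at 1.04, and cyclin CCNB1 had 872 FPKM in the control and 267 with YK (0.99). Tubulins and microtubule-associated proteins had 1 of 32 higher, 2 lower and a median of -0.19 at percentile 0.85, which was 8.08 on deposited values and 4.13 after correction for expression level, length and GC content. That median was -0.33 on deposited ratios relative to the median gene and -0.079 without a filter on low values. TUBA4A, an alpha-tubulin, was higher at 1.92, and DCX, doublecortin, was lower at -1.19. The APC/C and SCF ubiquitin ligase genes had a median of 0.07, with UBE2S at 1.08 the 1 higher gene of 25.

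Interferon response genes had 4 of 19 higher with YK and a median of 0.48 at percentile 99.99, with ISG15 at 1.44 and IFIT3 at 1.43, although the median was -0.087 among genes with a mean FPKM of at least 5, 0.78 with a pseudocount of 0.1 and 1.09 on deposited ratios relative to the median gene. Replication-dependent histones had 3 of 16 lower and a median of -0.49, below all random lists, with HIST1H1C at -1.85 and HIST1H1E at -1.67, and neuronal markers had 3 of 10 lower and a median of -0.57, with NEFH, a neurofilament, at -1.34, at percentile 0.01, which was 2.96 on deposited values. Without a filter on low values these medians were 0.037 and 0.15, and the neuronal median was -0.17 among genes with a mean FPKM of at least 5. Cytosolic ribosomal proteins had 0 of 65 past the threshold and a median of 0.18 at percentile 99.6, which was -0.32 on deposited ratios relative to the median gene. The remaining lists lay within the middle 95% of random lists, but after correction for expression level, length and GC content p53 targets lay at percentile 98.7 and the stress response list at 98.4. Their medians were 0.21 for p53 targets, where the death receptor FAS was at 1.46, 0.12 for the stress response list, where the amino acid transporter SLC7A5 was at 1.79, and 0.11 for immediate early genes. Cholesterol synthesis stood at 0.09, hypoxia and glycolysis at 0.06, the BCL2 family at 0.04, NRF2 targets at -0.0038 and splicing factors at -0.0078, where HNRNPK was lower at -1.15. Proteasome subunits stood at -0.07 and heat shock genes at -0.12, where the small chaperone CRYAB was at 3.78. Fibroblast and endothelial markers had a median of 0.00064.

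**Figure D3:**
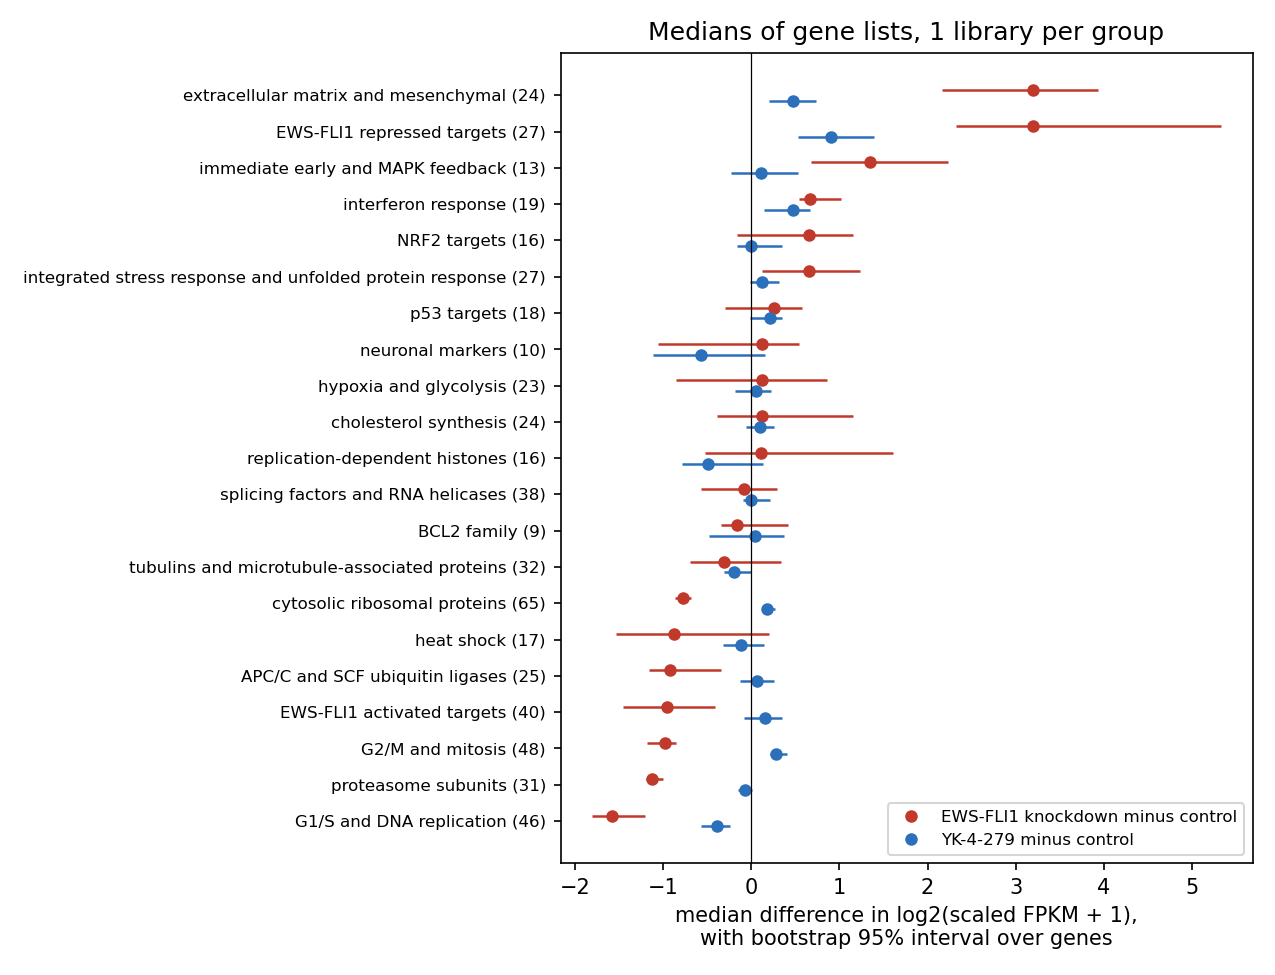
Median difference in log2(scaled FPKM + 1) from the control for each gene list with at least 5 measured genes, for the knockdown and YK libraries, with bootstrap 95% intervals over genes as lines and the number of genes in brackets. The repressed target list lies at 3.19 and 0.90, the activated target list at -0.95 and 0.16, and the G2/M list at -0.98 and 0.28.

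The 2 treatments were also set directly against each other. As deposited, 505 genes were higher and 2136 lower with YK than in the knockdown library, and after scaling 1516 were higher and 1442 lower. LGALS1, CCK, S100A6 and CES1 were among the 5 highest with YK, at relative log2 ratios of 5.92, 6.11, 5.63 and 5.51, beside MALAT1, whose listed 0 in the knockdown library can be a locus that was not estimated. KRT19P2,MIR492 at -8.28, CPA4 at -5.48, PTX3 at -5.19, EFEMP1 at -5.10 and FABP4 at -4.99 were the lowest. Activated fusion targets had 26 of 40 higher with YK and a median of 1.56, or 1.01 after correction for expression level, length and GC content. Repressed targets had 21 of 27 lower and a median of -2.10, or -3.17 among genes with a mean FPKM of at least 5. Of the G2/M genes, 30 of 48 were higher with YK, with a median of 1.29, and of the G1/S genes 21 of 46, with a median of 0.98. Abundant genes were generally higher with YK than after knockdown, so matched random lists had medians of 0.60 and 0.43, and the corrected medians of the G2/M and G1/S lists were 0.85 and 0.66. Matrix and mesenchymal genes had 19 of 24 lower and a median of -2.48, and immediate early genes 7 of 13 lower and a median of -1.31. Without a filter on low values these medians were -1.59 and -0.85. Tubulins had 8 of 32 higher and 8 lower, with a median of 0.11.

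Across genes, the differences of both treatments from the control were correlated. After scaling, Pearson's r was 0.41 and Spearman's rho 0.42 over 9939 genes, which are not independent replicates, and as deposited r was 0.74. Unchanged libraries drawn against 1 shared control over the 8750 genes with a length gave r of 0.45 from counting error alone, where the same genes had an observed r of 0.42. The simulated covariance was 0.0040 against 0.29 observed, and the simulation holds no differences between cultures or preparations. After scaling, 113 genes were higher in both, where independent lists would share 41.4, and 100 were lower in both, where they would share 28.6. These counts hold small nucleolar and Cajal body RNAs, and some of the genes counted were listed at 0 in the control or in a treated library. ACTA2, MGP, FN1 and CPA4 were among those higher in both, and ISOC1, WDR18, CCNE2 and EIF4EBP1 among those lower in both. Higher in the knockdown library and lower with YK were 5 genes, where independent lists would share 28.99, and the reverse held for 14 against 40.8. As deposited, 27 genes were higher in both against 1.73 for independent lists, and 7033 were lower in both against 6538. On that scale 67 were higher after knockdown and lower with YK against 277, and the reverse held for 4 against 40.7. The control was 1 library that could not be divided, so the excess, in part or in whole, may come from it.

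**Figure D4:**
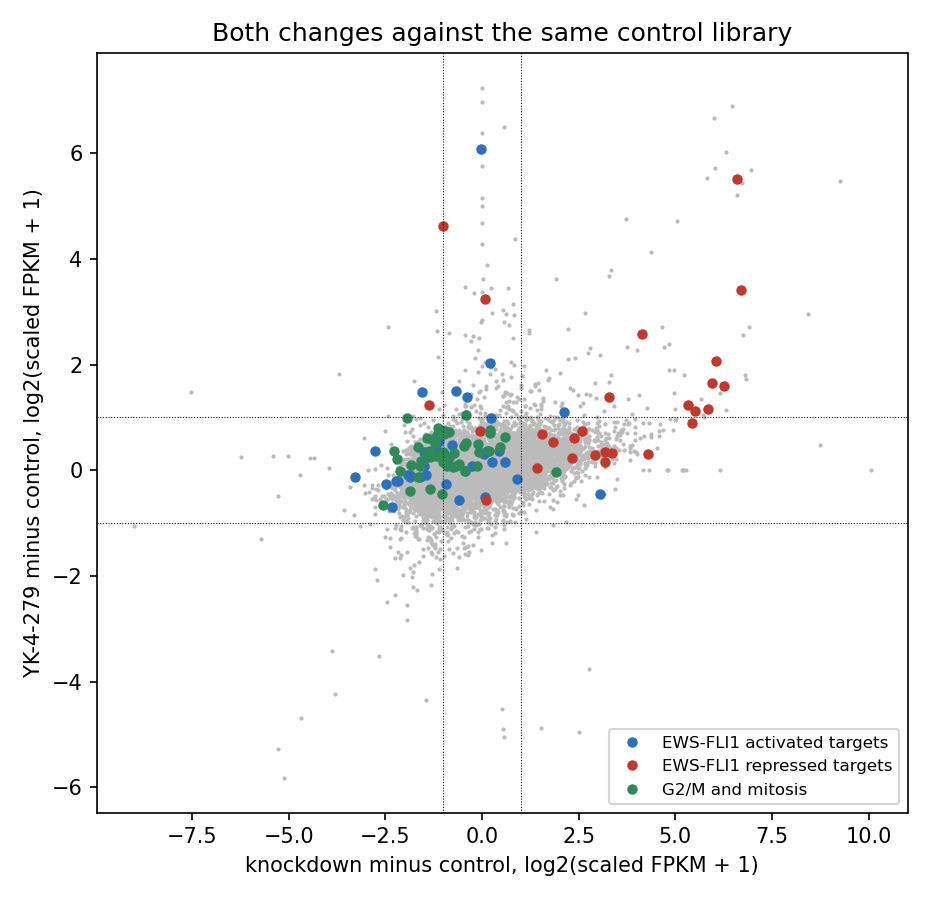
Difference from the control in log2(scaled FPKM + 1) for 9939 genes, knockdown on the x axis and YK on the y axis, with each point 1 gene and dotted lines at -1 and 1. Repressed targets spread to the right and upward, activated targets mostly to the left, and Pearson's r over all genes is 0.41.

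Among markers of other cell types, blood cell markers had 2 of 14 measured, with medians of -0.66 in the knockdown library and -0.04 with YK. Epithelial markers had 2 of 11 measured, with medians of 0.93 and 0.94. None of the mitochondrial-encoded genes was measured under its own name.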

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

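The tests weighed for the overall shift, for the genes high with YK and of length and GC content were chosen after the results were seen; those on expression level in the other library, on background fragments and on range compression were written before their values were known.

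Genes listed as activated by EWS-FLI1 and cytosolic ribosomal proteins drew attention because their medians had opposite signs in the 2 treatments and lay far out among random lists in both. Activated targets had medians of -0.95 after knockdown and 0.16 with YK, and ribosomal proteins -0.78 and 0.18. The ribosomal median after knockdown lay at percentile 99.0, above most genes of like abundance, so its negative sign goes with the trend of abundant genes in that library. On deposited values the same rule picks genes listed as repressed by the fusion, with medians of 2.16 after knockdown and -0.26 with YK, and matrix and mesenchymal genes, with 1.61 and -1.38. Those signs hold the overall shift of the deposited scale, and relative to the median gene both lists were high in both treatments. None of these differences between treatments was tested, since each group has 1 library.

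The median unnamed locus was higher in both treated libraries, but the sum over unnamed loci was not. At the median of loci above 0 in all 3 libraries, unnamed loci held 4.42 times as many estimated fragments in the knockdown library as in the control and 6.36 times as many with YK, while named genes had 1.17 and 1.28 times fewer. Unnamed loci took 49.9% of the FPKM sum in the control, 56.7% after knockdown and 48.5% with YK. Divided by the worth of 1 fragment, their sum was 0.741 and 0.726 of that in the control. The 100 most abundant unnamed loci held at least 95.8% of it in each library, and the others together were 3.77 and 5.10 times the control. This bears on the low FPKM of most named genes in the treated libraries. Fewer sequenced gene fragments are argued against as the whole cause. The median log2 ratio of estimated fragments per named gene went no lower than -0.35. In total the compared genes did hold fewer, at 14788900 after knockdown and 18050178 with YK against 24501270 in the control. A scaling that followed the many unnamed loci may account for the low FPKM, as the median log2 ratio of these loci stayed within 0.35 of 0. Less messenger RNA per cell cannot be told apart from more background in the library, because the median unnamed locus was higher by at least 2.14 on the log2 scale in estimated fragments while the sum was lower, and no spike-in was used here.

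Abundant genes were low and scarce genes high in the knockdown library. Ranking genes by the control's own values does not account for it, because the knockdown ratio had a Spearman rho of -0.57 with the level in the YK library, which does not enter the ratio. Length and GC content left rho at -0.51 after correction. Background fragments added to scarce genes are argued against as the whole cause, with rho still at -0.26 among the 3490 genes at a scaled FPKM of at least 10, although part of the trend may come from them. Range compression in library preparation and a change in the cells cannot be told apart: the slope of the knockdown level on the YK level was 0.86, which either would give, against 0.97 for the control.

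The 10 genes highest with YK included LGALS1, CCK, MGP and ACTA2, and 7 of the 10 had less than 1 FPKM in the control. A general bias of short transcripts is argued against. The 1597 genes no longer than the median length of these, known for 8 of the 10, had a median relative log2 ratio of 0.058 with YK. A bias limited to short genes scarce in the control was not tested. Fibroblasts mixed into the culture are argued against as the source of LGALS1, since COL1A1 and COL1A2 together reached only 0.0028 of its FPKM, at 0.515 and 0.192 FPKM. That ratio cannot exclude a small admixture that raised scarcer genes, or cells poor in these collagens. Lower function of EWS-FLI1 stays open. Of the 10 genes, 3 were also higher in the knockdown library, where 17.3% of all compared genes were, and both ratios use the same control. The target lists did not settle it, as 13 of 27 repressed targets were higher with YK while 0 of 40 activated targets were lower. A difference between cell stocks also stays open, untested.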

How the results depend on the processing

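The scale for single genes and lists, division by the worth of 1 fragment, and the correction for level, length and GC content were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The alternatives on estimation status and confidence bounds were not run. The planned counts as deposited, 301 higher and 7094 lower after knockdown, 57 and 9160 with YK, and 505 and 2136 for YK against knockdown, depend on the scale, since the median gene itself shifts. Rescaled to a common sum they were 2525 and 903, 238 and 153, and 884 higher in the last. Centring gave 2206 and 2342, 1225 and 446, and 1121 and 1181. Scaling on the median gene gave 1715 and 1689, 240 and 168, and 1516 higher in the last. Division by the worth of 1 fragment gave 1766 and 2560, 251 and 722, and 1348 higher in the last. A threshold of 2 gave 129 and 4277, 32 and 5941, and 61 and 439. A mean FPKM of at least 5 left 123 higher after knockdown, 32 higher and 5784 lower with YK, and 1123 lower in the last. With a pseudocount of 0.1, 3468 genes were lower in the last. Correlation of both changes was 0.74 as deposited, 0.40 rescaled to a common sum, 0.41 scaled on the median gene and 0.48 per fragment. Of the list medians, 519 of the values under alternatives stayed within the bootstrap interval, 44 moved out of it, and 10, of lists outside the middle 95% of random lists, changed sign. Of the 519 and the 44, 38 and 3 values of lists within that middle changed sign too. On deposited values relative to the median gene, medians after knockdown were -1.27 for G2/M, -1.82 for G1/S, -1.27 for ubiquitin ligases, -1.502 for proteasome, -1.17 for ribosomal proteins and 1.35 for epithelial markers. With YK they were 1.94 for repressed targets, -0.85 for G1/S, -0.33 for tubulins, -0.42 for heat shock, -0.40 for splicing factors, -0.54 for proteasome, 1.09 for interferon genes, 0.78 for immediate early genes, 0.83 for matrix genes and 1.45 for epithelial markers, and the sign turned for G2/M at -0.11, ribosomal proteins at -0.32, ubiquitin ligases at -0.18 and cholesterol synthesis at -0.21. Between treatments ribosomal proteins were at 0.81 and splicing factors turned to -0.045. The pseudocount acting on libraries of different scale shifts these by construction. Corrected for level, length and GC content, medians after knockdown were -0.35 for G2/M, -1.10 for G1/S, -0.056 for ubiquitin ligases, -0.45 for the BCL2 family, -0.13 for proteasome, 0.53 for interferon genes and 0.59 for epithelial markers, and turned to 0.26 for splicing factors and 0.10 for ribosomal proteins. The corrected epithelial median with YK was 0.87. Between treatments the corrected medians were 0.85 for G2/M, 0.32 for ubiquitin ligases, 0.069 for proteasome, 0.092 for ribosomal proteins and 0.31 for epithelial markers, and turned to -0.21 for splicing factors. With a pseudocount of 0.1, interferon genes were at 1.02 after knockdown and 0.78 with YK, epithelial markers at 1.43 and 1.47, repressed targets at 1.54 with YK, and activated targets at 1.77 between treatments. With a mean FPKM of at least 5, NRF2 targets turned to -0.17 after knockdown and interferon genes to -0.087 with YK, and immediate early genes with YK turned to -0.23. With no filter, matrix genes were at 1.96 after knockdown and -1.59 between treatments, epithelial markers at 0.083 and 0.090, and neuronal markers and histones with YK turned to 0.15 and 0.037. Rescaled to a common sum, epithelial markers with YK were at 0.88. Apart from the scale and the filters, the cause was not tested. No named gene past the threshold changed sign under the alternatives run, with 445 of the values moved beyond counting error and 872 not. Those alternatives kept values relative to the median gene, so they could not show the effect of the overall shift. On deposited FPKM some signs differ. GTSE1 had 35.8 in the control and 11.8 with YK, and TUBA4A had 8.77 and 6.41, though both were higher after scaling. Of the lists outside the middle 95% of random lists, 10 of 10 after knockdown, 8 of 10 with YK and 10 of 10 between treatments were outside on the same side on deposited values, where 0, 0 and 1 others were outside too. After the correction these were 10 of 10, 9 of 10 and 8 of 10, with 2, 3 and 2 others. With YK tubulins left on both and neuronal markers on deposited values, and p53 targets, the stress response list and epithelial markers, at percentile 98.0, entered after the correction. Depth limits genes with few fragments, and with 1 library per group no spread between cultures is known.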

Other observations

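Some small nucleolar and Cajal body RNAs, which the rule for named genes leaves out, were counted as higher in both treatments and others as lower in both. The class was not tested as a list. SNORA21, SNORA3, SNORA56 and SCARNA21, which guide chemical modification of other RNAs, were listed at 0 in the control and at 54.9, 44.8, 85.7 and 60.5 FPKM in the knockdown library, with 30.2, 24.4, 23.7 and 55.7 FPKM with YK. SNORA55 and SNORA68 were at 116 and 76.4 FPKM in the control and listed at 0 in both treated libraries. A listed 0 was not read as absence, and FPKM of such short transcripts rests on few fragments and on the length the authors' tool assumed, and these genes were chosen after their values were seen.

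Single genes from no common group, also chosen after their values were seen, were higher in both treatments on the scaled values. IFI16, a DNA sensor, had relative log2 ratios of 2.67 after knockdown and 2.97 with YK, CRYAB had 3.33 and 3.78, and TMSB4X, an actin-binding peptide, had 4.83 and 2.39. The nuclear RNA NEAT1 had 4.13 FPKM in the control, 50.3 in the knockdown library and 3.64 with YK, with relative log2 ratios of 4.97 and 1.89, while its neighbour MALAT1 was listed at 0 in the knockdown library. The receptor KIT had 2.75 and 2.21. Among genes lower in both, SHMT2, of mitochondrial one-carbon metabolism, had -1.80 and -2.03.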
